A study of Mus musculus with 17 samples.

How the data were processed

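Total RNA of sorted spleen B-lineage cells was labelled with biotin and hybridised to 1 array per sample, per the labels' protocols. The deposited values are on a log2 scale, and were made with RMA per the submitters' processing notes, with no version given. Whether all arrays were normalized together is not given in the sources used here, and scanner files were not used here. The deposited table lists 41801 rows, of which 8474 were blank in every array and were left out, 190 of these being control rows, and 33327 held log2 values in all 17 arrays. The platform annotation pairs 23365 of the valued rows with 1 gene symbol, 1774 with several and 8188 with none. In 6 groups the arrays were compared by genotype within each population, by population within control mice, and for a difference of the genotype effect between populations, 9 comparisons in all. The groups, the comparisons, the tests, the gene lists and most alternatives were fixed before the data were examined.

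The values were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off, 2-sided). Each group had a mean of its own in a fit of all 17 arrays, with 11 residual degrees of freedom and one estimate of the spread per probe set. P-values were adjusted by Benjamini-Hochberg within a comparison and called under 0.05. A probe set was tested if it exceeded the 50th percentile of its array in at least 2 arrays, which left 19350. The pooled spread lends the more variable IgM+CD138+ arrays some precision from the other populations, so the fit of only the compared groups is given as an alternative.

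The plan had been to test 1 probe set per annotated gene. This was changed after the values were seen, because the annotated names were not borne out by the levels, and all valued probe sets that passed the brightness filter were tested. The planned set of 13034 probe sets is an alternative. The rule for named genes (the targeted gene Myb, list members, and the 10 largest changes in each direction among called genes whose arrays do not overlap) was not applied to changed probe sets for the same reason, and a further item that the rule names is not reported here. The check of names compared bright with silent gene families at 601 evenly growing displacements in steps of 5 rows. The families were chosen after the mismatch had been noticed, from general knowledge of where they are expressed. A realignment of single rows to the annotation was also tried during the work, with different results from different starting points, and no value or name from it is used. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, on the planned set with names as paired.

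The limma step was tested on simulated data with the real means and spreads of the 19350 probe sets. For the genotype comparison in IgM+CD138+ cells it recovered 87% of 100 probe sets changed by 2-fold and 96% of 100 changed by 4-fold, with 3 false calls. In B220+CD23+ cells it recovered 92% and 98% with 15 false calls, and in B220+CD23-IgM+ cells 79% and 100% with 7 false calls. The simulation gave each array the same spread, which the real groups do not have. It also drew every probe set and array independently, whereas deviations of real arrays from their group means correlated at up to 0.409. Its false calls therefore need not match those in the real data. The number of arrays limits the precision. Between arrays of one group the lowest standard deviation of the difference over all rows was 0.27 log2, so no array was a copy of another. Alternatives covered the filter, the normalization, the probe sets tested, the variance model, the arrays in the fit, array weights, a block for the replicate number or mouse, a fold threshold and leaving out each array. Figures were drawn with matplotlib 3.10.9.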

Results

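The measurements were microarray expression values of B-lineage cells sorted from mouse spleen. All mice were of one atherosclerosis-prone background and had been kept on a cholesterol-rich diet over 12 weeks. Control mice are labelled with this background alone, and the other genotype is named c-myb h/h in the labels, with Myb being a transcription factor of blood cell development. From each genotype 3 cell populations were sorted, IgM+CD138+ cells (CD138, or syndecan-1, marks antibody-secreting cells), B220+CD23+ cells (CD23 marks follicular B cells) and B220+CD23-IgM+ cells. Each group held 3 arrays, except control B220+CD23-IgM+ cells with 2, giving 17 arrays in 6 groups. The design text describes separate mice. Arrays of one genotype with the same number were taken as one mouse that gave several populations, which the labels do not state outright. On that reading the same mice supply both sides of a population comparison, and the main fit did not pair them. The number of arrays limits the precision, and the median log2 value of an array lay between 5.13 and 5.21.

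IgM+CD138+ arrays stood apart from those of the other populations far more than the genotypes did from each other. The first principal component held 67.8% of the variance and placed the 6 arrays of IgM+CD138+ cells at scores from -73.1 to -56.3, away from B220+CD23+ and B220+CD23-IgM+ cells at 27.3 to 42.9. The second component held 7.20%. Pearson correlations over all probe sets had a median of 0.990 between arrays of one B220+CD23+ group, 0.985 between B220+CD23+ and B220+CD23-IgM+ arrays, 0.948 between B220+CD23-IgM+ and IgM+CD138+ arrays, and 0.941 between B220+CD23+ and IgM+CD138+ arrays. Between genotypes the median was 0.988 within B220+CD23+ cells, 0.987 within B220+CD23-IgM+ cells and 0.979 within IgM+CD138+ cells. B220+CD23+ and B220+CD23-IgM+ arrays were thus slightly less similar to each other than arrays of the 2 genotypes within either population. They were more similar than IgM+CD138+ arrays of the 2 genotypes, whose median of 0.979 was close to the 0.980 between arrays of one IgM+CD138+ group. The pairs of arrays between populations included both genotypes. IgM+CD138+ arrays varied more within their group, with a median standard deviation per probe set of 0.182 in control and 0.167 in c-myb h/h mice, against 0.130 and 0.121 for B220+CD23+ cells.

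**Figure D1:**
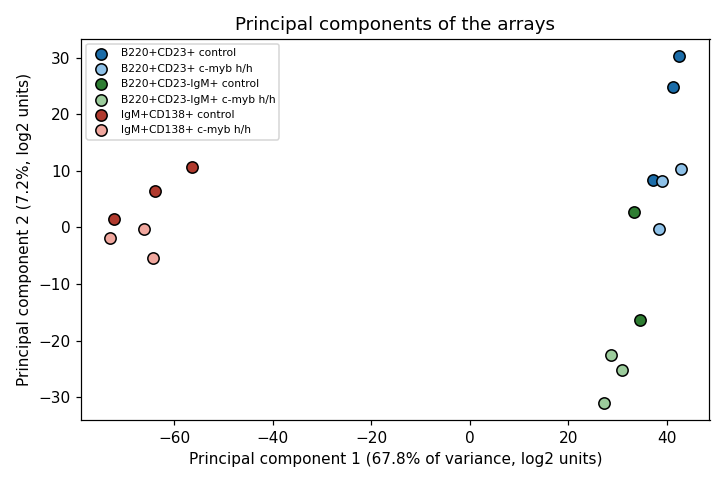
Scores of the 17 arrays on principal components 1 (horizontal, 67.8% of variance) and 2 (vertical, 7.20%) of the tested log2 values, 1 point per array and 1 colour per group. The IgM+CD138+ arrays lie at -73.1 to -56.3 on the horizontal axis and all others at 27.3 to 42.9.

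The names that the platform annotation pairs with the probe IDs were compared with the levels, and for broad gene families they were not borne out. Probe sets paired with families that nearly every cell uses (such as ribosomal, proteasome and splicing genes; 719 listed probe sets) had a mean level 0.21 log2 below that of probe sets paired with families silent outside their own tissue (such as olfactory receptors and keratins; 2065 listed probe sets), the signed difference being -0.21. This difference was below 0 on each array, from -0.25 to -0.19. The brighter of the probe sets paired with Sdc1, the gene of the CD138 used for sorting, read 8.20 ± 0.23 (SD, n = 3) in control IgM+CD138+ cells and 8.32 ± 0.16 (SD, n = 3) in control B220+CD23+ cells. The probe set paired with Fcer2a, the gene of CD23, read 6.46 ± 0.17 (SD, n = 3) in control B220+CD23+ cells and 6.76 ± 0.05 (SD, n = 3) in control IgM+CD138+ cells. The brightest of the 7 probe sets paired with Ighm, the gene of the IgM heavy chain, did read higher in control IgM+CD138+ cells (11.55 ± 0.06, SD, n = 3) than in control B220+CD23+ cells (7.25 ± 0.22, SD, n = 3). The probe set paired with Ptprc, the gene of B220, read 7.87 ± 0.07 (SD, n = 3) and 8.03 ± 0.19 (SD, n = 3) in that order, a difference within the spread of the B220+CD23+ arrays. With the values displaced along the list by an amount growing evenly to 385 rows at its end, the same families differed by 1.70 log2, whereas displacements more than 100 rows from this gave at most 0.59. Probe sets are therefore reported by population and count, and no gene name is given to a changed probe set.

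**Figure D2:**
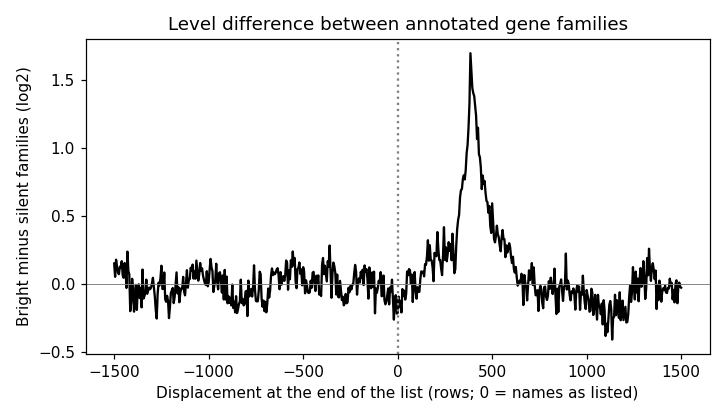
Mean log2 level of probe sets paired with broadly used families minus that of probe sets paired with silent families (vertical), against the displacement in rows reached at the end of the list (horizontal, 0 being the names as listed). The line stands at -0.21 for the names as listed and peaks at 1.70 for a displacement of 385 rows.

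The targeted gene could not be used to check the genotype labels for the same reason. The brighter of the probe sets paired with Myb differed between c-myb h/h and control by -0.15 log2 in IgM+CD138+ cells (limma adjusted p = 0.857), 0.05 in B220+CD23+ cells (limma adjusted p = 0.996) and -0.01 in B220+CD23-IgM+ cells (limma adjusted p = 0.996). Of 270 tests of gene lists fixed before the data were examined (30 lists in 9 comparisons, names as paired), 2 passed with camera's preset correlation and 0 with an estimated correlation, and no list is described further because its names were not borne out.

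The comparison of IgM+CD138+ with B220+CD23+ cells asked how the CD138-bearing population differs from CD23-bearing B cells in control mice. Of 19350 probe sets tested, 8208 differed (limma, Benjamini-Hochberg adjusted p under 0.05), 3589 higher and 4619 lower in IgM+CD138+ cells. The large differences lay on the higher side. In IgM+CD138+ cells 481 probe sets were higher by at least 4-fold and 98 lower by as much, 86 were higher by at least 16-fold and 0 lower, and the extremes were 6.75 and -3.03 log2. The median difference over all tested probe sets was -0.083 log2, an offset that adds to the lower calls. Requiring 1.5-fold left 4798 probe sets, 2465 higher and 2333 lower, and the excess of lower calls was gone. The 481 probe sets were not spread evenly over the list. Windows of 100 listed rows held 50 of them (rows 31101 to 31200), 48 (rows 12701 to 12800), 47 (rows 12601 to 12700) and 32 (rows 30201 to 30300), whereas 1000 random draws put at most 10 in a window. The same populations in c-myb h/h mice, which are other animals, gave 8344 differing probe sets, and 6405 of the 8208 differed in the same direction there, against 1792.5 for independent lists. A further 10 differed in the opposite direction. The 2 genotypes share the spread of each probe set in the fit, which the values for independent lists leave out here and below.

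IgM+CD138+ cells also differed widely from B220+CD23-IgM+ cells in control mice. Of the probe sets tested, 6780 differed, 2964 higher and 3816 lower in IgM+CD138+ cells, with 398 higher and 96 lower by at least 4-fold. In c-myb h/h mice 7305 differed, and 5261 did so in the same direction as in control mice, against 1303.9 for independent lists. With only these 2 groups in the fit the control count was 4325, and the excess of lower calls was gone (2180 higher and 2145 lower). Requiring 1.5-fold left 4337 (2157 higher and 2180 lower). The median difference over all tested probe sets was -0.068 log2.

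B220+CD23-IgM+ cells differed from B220+CD23+ cells in far fewer probe sets. In control mice 294 of 19350 differed, 228 higher and 66 lower in B220+CD23-IgM+ cells, with 20 higher and 3 lower by at least 4-fold. In c-myb h/h mice 569 differed (393 higher, 176 lower), and 196 of the 294 did so in the same direction, against 5.23 for independent lists. The control count rests on 2 and 3 arrays, and it fell to 77 without control B220+CD23-IgM+ replicate 1, 169 without replicate 2 of that group, 110 without control B220+CD23+ replicate 2 and 107 without its replicate 3. It was 169 with only these groups in the fit, 195 with ordinary least squares and 544 with array weights.

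Between genotypes, few probe sets passed the adjusted threshold in any population. At an unadjusted limma p under 0.05 lay 2042 in IgM+CD138+ cells, 1248 in B220+CD23+ cells and 1675 in B220+CD23-IgM+ cells. Chance gives 967.5 on average if all groups have one spread. IgM+CD138+ arrays varied more than the others, and probe sets can vary together, so these counts alone do not show an effect of genotype. After adjustment, in IgM+CD138+ cells 37 differed, 19 higher and 18 lower in c-myb h/h mice, of which 12 in each direction reached 2-fold and the extremes were 3.32 and -3.30 log2. With only the IgM+CD138+ arrays in the fit the count was 0, with ordinary least squares 13 and with the arrays centred and scaled 73 (45 higher and 28 lower). Without control replicate 1 it was 83 (31 higher and 52 lower). It was 64 without control replicate 3 (38 higher and 26 lower) and 68 without c-myb h/h replicate 1 (43 higher and 25 lower). The balance of directions thus changed with the array left out. Another division of these 6 arrays, which set control replicates 1 and 2 with c-myb h/h replicate 1, gave 35. The probe set at -3.30 log2 stood at listed row 30222, inside a window given above as dense in probe sets higher in IgM+CD138+ cells. Listed rows 12623 (2.71 log2), 12694 (-2.61) and 12746 (-1.57) also lay in such windows. The others of the 10 largest called changes in each direction without overlap, such as 3.32 at row 40129, lay outside them. What this means for these differences was not tested.

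In B220+CD23+ cells 26 probe sets differed between genotypes, 19 higher and 7 lower in c-myb h/h mice, with 12 higher and 5 lower by at least 2-fold. The count moved with every array left out, to 50, 4 and 6 without control replicates 1, 2 and 3, and to 7, 10 and 4 without c-myb h/h replicates 1, 2 and 3. It was 130 with array weights (97 higher and 33 lower), 44 with the arrays centred and scaled (37 higher and 7 lower), 44 with trend and robust moderation and 10 with ordinary least squares. With only the B220+CD23+ arrays in the fit it was 38 (27 higher and 11 lower).

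In B220+CD23-IgM+ cells 8 probe sets differed between genotypes, 6 higher and 2 lower in c-myb h/h mice. The count was 0 with only these arrays in the fit, 2 with the arrays centred and scaled (1 in each direction), 18 with trend and robust moderation, 22 with array weights, and 4 with 1 probe set per annotated gene or with probe sets paired with 1 gene. It was 47 and 1 without control replicates 1 and 2, and 2, 2 and 52 without c-myb h/h replicates 1, 2 and 3.

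Across the 3 populations 63 probe sets differed by genotype in at least 1 population and 7 in more than 1, all 7 in the same direction wherever they passed. With only the compared groups in each fit only B220+CD23+ cells had calls, so the count in more than 1 population had to be 0. The 7 became 4 with the arrays centred and scaled, 3 with ordinary least squares and 13 with array weights. They became 4 without control B220+CD23+ replicate 2, c-myb h/h B220+CD23+ replicate 3, control B220+CD23-IgM+ replicate 2, or c-myb h/h B220+CD23-IgM+ replicate 1 or 2, 13 without control B220+CD23-IgM+ replicate 1, and 15 without c-myb h/h B220+CD23-IgM+ replicate 3. The overlap between IgM+CD138+ and B220+CD23+ cells was 3 (0.025 for independent lists), between IgM+CD138+ and B220+CD23-IgM+ cells 2 (0.0078), and between B220+CD23+ and B220+CD23-IgM+ cells 4 (0.0066). These comparisons share no arrays, but arrays of one genotype with the same number were taken as the same mouse, and the values for independent lists leave that out. Deviations of such arrays from their group means correlated between B220+CD23+ and B220+CD23-IgM+ cells at 0.409 and 0.297 in control mice and at 0.201, 0.065 and 0.038 in c-myb h/h mice. Of the 7, the 2 with the most negative and the 2 with the most positive mean difference are given by their listed ID, a choice made after their values were seen. The pairing of a listed ID with its values is open to the displacement described above.

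Listed probe set 17544267 was lower in c-myb h/h mice in all 3 populations. It differed by -1.59 log2 (SE 0.16) in IgM+CD138+ cells, from 7.14 ± 0.08 (SD, n = 3) in control to 5.55 ± 0.29 (SD, n = 3). The difference was -1.38 (SE 0.16) in B220+CD23+ cells and -2.23 (SE 0.18) in B220+CD23-IgM+ cells. The limma adjusted p-values were 0.00171, 0.00356 and 8.7e-05 in that order. With only the compared groups in each fit they were 0.138, 0.0205 and 0.0839, which ended the calls in IgM+CD138+ and B220+CD23-IgM+ cells. In the other alternatives that tested this probe set its 3 calls held. Listed probe set 17445268 was lower by genotype in IgM+CD138+ cells (-1.17 log2, limma adjusted p = 0.0197) and B220+CD23+ cells (-1.25, limma adjusted p = 0.0191), and its difference in B220+CD23-IgM+ cells was -1.04 (limma adjusted p = 0.102). Listed probe set 17283573 was higher in c-myb h/h B220+CD23+ cells (1.94 log2, limma adjusted p = 0.00444) and B220+CD23-IgM+ cells (1.87, limma adjusted p = 0.020), and differed by 0.57 in IgM+CD138+ cells (limma adjusted p = 0.42). It stood at listed row 12624. In its window, rows 12601 to 12700, 47 of 72 tested probe sets were at least 4-fold higher in IgM+CD138+ than B220+CD23+ cells. Its own control means were 9.92 and 7.21 in that order. Listed probe set 17468143 was higher in c-myb h/h B220+CD23+ cells (1.09 log2, limma adjusted p = 0.0226) and B220+CD23-IgM+ cells (1.63, limma adjusted p = 0.00689), and differed by 0.30 in IgM+CD138+ cells (limma adjusted p = 0.614). With only the compared groups in each fit, the limma adjusted p-values in B220+CD23+ cells were 0.0159, 0.0205 and 0.0411 for these 3 probe sets in that order. The same fit ended the call of 17445268 in IgM+CD138+ cells (limma adjusted p = 0.333), and those of 17283573 and 17468143 in B220+CD23-IgM+ cells (limma adjusted p = 0.206 and 0.241). Single arrays ended calls of these 3 as well. In B220+CD23+ cells 17445268 and 17468143 lost their calls without any array of that population except control replicate 1 (limma adjusted p up to 0.110 and 0.178), and 17283573 did without control replicate 2 (0.0519). In IgM+CD138+ cells 17445268 lost its call without c-myb h/h replicate 2 (0.0619). In B220+CD23-IgM+ cells 17283573 lost its call without control replicate 2 (0.526) or c-myb h/h replicate 1 (0.113) or 2 (0.0659), and 17468143 without control replicate 2 (0.172). Ordinary least squares ended both calls of 17445268 (adjusted p = 0.102 and 0.0824), that of 17468143 in B220+CD23+ cells (0.113) and that of 17283573 in B220+CD23-IgM+ cells (0.106), the last also being lost with the arrays centred and scaled (0.0506).

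**Figure D3:**
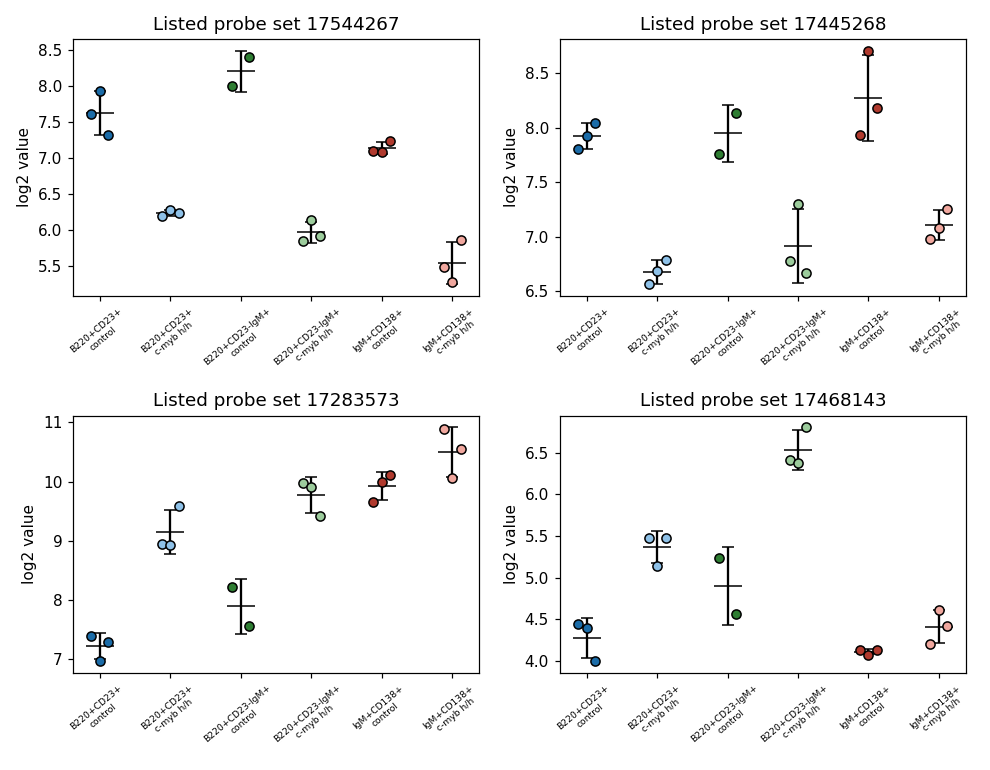
Log2 values (vertical) of 4 listed probe sets in the 6 groups (horizontal), with 1 point per array, a horizontal bar at the group mean and error bars of 1 SD. Probe set 17544267 lies lower in c-myb h/h than in control arrays in each population.

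With all arrays in the fit, no probe set passed limma's test of whether the genotype difference itself differed between populations. The limma count was 0 for IgM+CD138+ against B220+CD23+ cells (1303 at an unadjusted p under 0.05, lowest limma adjusted p = 0.0795). It was 0 for B220+CD23-IgM+ against B220+CD23+ cells (750 unadjusted, lowest limma adjusted p = 0.896). It was also 0 for IgM+CD138+ against B220+CD23-IgM+ cells (1375 unadjusted, lowest limma adjusted p = 0.404). Chance gives 967.5 unadjusted calls on average, again if all groups have one spread. Ordinary least squares gave 1, 0 and 0. The first count was 5 without control IgM+CD138+ replicate 1, 5 without its replicate 2, 1 without c-myb h/h IgM+CD138+ replicate 1 or 3, 2 with trend and robust moderation, and 1 with array weights, with the arrays centred and scaled, or with 1 probe set per annotated gene. The second was 0 under every alternative run. The third was 2 without control B220+CD23-IgM+ replicate 1 and 1 without control IgM+CD138+ replicate 2 or 3 or c-myb h/h IgM+CD138+ replicate 1.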

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

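The test on 1 probe set per annotated gene was planned as the main set and became an alternative after the data were seen. The cause of a moved count was not tested unless stated. Leaving out each array in turn gave, against the full counts, 27 to 83 for genotype in IgM+CD138+ cells (37), 4 to 50 in B220+CD23+ cells (26) and 1 to 52 in B220+CD23-IgM+ cells (8). For the populations in control mice it gave 6954 to 8140 for IgM+CD138+ against B220+CD23+ (8208), 77 to 295 for B220+CD23-IgM+ against B220+CD23+ (294) and 4735 to 7014 for IgM+CD138+ against B220+CD23-IgM+ (6780). For the differences of genotype effects it gave 0 to 5, 0 to 0 and 0 to 2, the highest without control IgM+CD138+ replicate 1 or 2 and without control B220+CD23-IgM+ replicate 1. Where 1 array was left in control B220+CD23-IgM+ cells it was assumed to vary like the other groups. For probe sets called by genotype in more than 1 population (7) it gave 4 to 15, a count whose alternatives were all chosen after the data were seen. For gene lists the range was 0 to 2, and for the Myb-paired probe set -0.23 to -0.03, -0.11 to 0.19 and -0.26 to 0.25 log2 in IgM+CD138+, B220+CD23+ and B220+CD23-IgM+ cells.

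Centring and scaling the arrays gave 73 probe sets by genotype in IgM+CD138+ cells (45 higher and 28 lower, against 19 and 18), 44 in B220+CD23+ cells (37 and 7, against 19 and 7) and 2 in B220+CD23-IgM+ cells (1 and 1, against 6 and 2), and 1 for the difference of genotype effects between IgM+CD138+ and B220+CD23+ cells. Trend and robust moderation gave 44 in B220+CD23+ cells, 18 in B220+CD23-IgM+ cells and 2 for that difference. Array weights gave 130 and 22 in those cells, 1 for that difference, and 544 for B220+CD23-IgM+ against B220+CD23+. With only the compared groups in the fit, which leaves fewer arrays, the counts were 0 for genotype in IgM+CD138+ cells, 0 in B220+CD23-IgM+ cells, 169 for B220+CD23-IgM+ against B220+CD23+ and 4325 for IgM+CD138+ against B220+CD23-IgM+. Least squares gave 13 and 10 for genotype in IgM+CD138+ and B220+CD23+ cells, 195 for B220+CD23-IgM+ against B220+CD23+, and 1 for the difference between IgM+CD138+ and B220+CD23+. Probe sets paired with 1 gene gave 4 for genotype in B220+CD23-IgM+ cells, and 1 per annotated gene gave 4 there and 1 for that difference, with fewer probe sets tested. Requiring 1.5-fold left 4798 and 4337 for IgM+CD138+ against B220+CD23+ and B220+CD23-IgM+. In c-myb h/h mice 569 probe sets differed between B220+CD23-IgM+ and B220+CD23+ cells. The 7 probe sets called by genotype in more than 1 population became 4 with centring and scaling, 13 with array weights and 3 with least squares. With only the compared groups they became 0, which the counts of 0 in IgM+CD138+ and B220+CD23-IgM+ cells fixed in advance. Gene list calls numbered 0 with an estimated correlation, 36 with fry, which does not compare a list with other genes, and 1 without the sort genes, against 2.

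With the replicate number as a block the genotype counts were 70, 44 and 25 in IgM+CD138+, B220+CD23+ and B220+CD23-IgM+ cells, the population counts 8376, 300 and 7078, and the differences of genotype effects 0, 0 and 0, with 1 gene list call and 13 probe sets called by genotype in more than 1 population. With the mouse as a random block (correlation 0.031) they were 36, 28 and 9, then 8358, 306 and 6933, then 0, 0 and 0. For the Myb-paired probe set the number block gave -0.15, 0.05 and -0.07 and the mouse block -0.15, 0.05 and -0.01 log2. The genotypes are different mice, so the number was not taken to pair them. The deviations from group means do not speak for that choice. Same-numbered arrays of one population deviated together across genotypes by over 0.1 in 5 of 8 pairs (correlations 0.032 to 0.345). As a hint from the data that it marks something shared, the number block moved each genotype count by over 1.5 times, and every control array correlated best with its own number in IgM+CD138+ cells (3 of 3) and B220+CD23-IgM+ cells (2 of 2), and 2 of 3 did in B220+CD23+ cells. Within a genotype a number was taken as one mouse, 9 of 16 such pairs of arrays deviated together by over 0.1, and the mouse block moved no count of probe sets by over 1.5 times.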

Other observations

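The tests on the annotated names, and the one on the second principal component, were chosen only after the result was seen. The second component, which runs from B220+CD23-IgM+ to B220+CD23+ cells, was also set against genotype. After subtracting the midpoint of each population, the 3 c-myb h/h mice averaged -7.2 ± 3.1 and the 3 control mice 7.24 ± 8.05 (SD over mice). An exact permutation test over mice gave a 2-sided p of 0.1, where 0.1 is the smallest that 3 mice against 3 allow, and arrays of one genotype with the same number were taken as one mouse.

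Probe sets paired with broadly used genes read no brighter than those paired with silent genes. Weak hybridisation or degraded RNA is argued against, because at the best displacement the bright families lay 1.63 log2 above the silent ones even on the lowest array. An annotation of an array design listed in another order is argued against as well. The check used rows with a mean at least 4-fold higher in control IgM+CD138+ than control B220+CD23+ cells, without brightness filter or test. At a displacement of 279 rows these rows fell on 88.2% of 17 annotated kappa variable segments. The share was at most 47.1% at displacements beyond 1000 rows and 0% as listed. Heavy chain segments, only 5, reached 100% at 71 rows. A candidate explanation is that the values are displaced along the list against their IDs: the family difference of 1.70 log2 at 385 rows lies 4.15 scan SDs above any value over 100 rows away, and its slope puts the kappa locus at 276.1 rows. Where such a displacement arose stays open. An ID list of a related design in the same order, with rows added or dropped, would give it too and was not tested apart, and no biological explanation was tested.

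Other divisions of the arrays were set beside the counts. For genotype in IgM+CD138+ cells 1 of 10 divisions reached the real count of 37, the highest other being 35. Divisions that kept both replicate 1 arrays together gave 35, 24, 21 and 0, and the third component placed these arrays at -23.1 and -22.3 with the other IgM+CD138+ arrays at 1.26 to 24.9, so arrays of that number share a structure that genotype does not explain. For genotype in B220+CD23+ cells 1 of 10 reached 26 (highest other 0). For IgM+CD138+ against B220+CD23+ cells in control mice 1 of 10 reached 8208 (highest other 0), and for gene lists there 1 of 10 reached 1 (highest other 0). The other divisions there mix the 2 populations, which puts their large difference into the spread. Low counts were thus given in advance, and no conclusion is drawn from these 2 tests. When the mice were divided between genotypes in all populations together, 1 of 10 reached the 7 probe sets called in more than 1 population (highest other 0). These divisions are too few for a share under 0.05. For the difference of the genotype effect between IgM+CD138+ and B220+CD23+ cells the real count was 0 and the highest other 2. Any division reaches a count of 0 (100 of 100 here), so this test decides nothing.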
